A study of Mus musculus with 12 samples.

How the data were processed

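Hippocampal RNA of control mice and of mice lacking CREB and CREM was measured on 12 Affymetrix arrays (array C of the murine genome U74 set), 3 for each combination of genotype and treatment. Per the labels the mice were littermates of both sexes, caged singly and handled before the experiment. They received kainate (20 mg/kg, intraperitoneal) or saline and were killed 1 hour later. Each array holds biotinylated cRNA from the pooled RNA of 3 animals, and the labels call the arrays biological replicates. The p-values therefore reflect differences between pools and not between single animals.

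The deposited table holds GCRMA values on the log2 scale, made by the authors in R 2.4.1 with a background adjustment by probe sequence, normalization across arrays and a summary per probe set. The GCRMA version and the control genotype's exact alleles are not given in the sources used here. Array medians ran from 3.26 to 3.41, 26.7 to 30.0% of probe sets reached log2 4 on an array, and correlations between arrays ran from 0.818 to 0.994. These values were used as deposited. The number of arrays, 3 per group, limits the precision of every difference.

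The table has 11934 probe sets. The 66 control probe sets were left out of the tests, and the 11868 others were filtered to those with a log2 value of at least 4 on at least 3 of the 12 arrays, which kept 3541 and left out 8327. Gene symbols came from the platform annotation and were checked against the mouse RefSeq gene table of assembly GRCm38.p6, used for names alone. Over the array 7717 probe sets had 1 symbol, 150 several and 4001 none, and 7699 of those with 1 symbol were found in the gene table. Of the kept probe sets 2713 had 1 symbol, 39 several and 789 none. Probe sets with several symbols or none were tested and counted but not named.

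Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with default settings). All 12 arrays entered a single model with a mean for each of the 4 groups, no block and 8 residual degrees of freedom. The comparisons were kainate against saline in control mice and in mutant mice, the interaction of genotype and kainate, mutant against control after saline and after kainate, and both main effects averaged over the other factor, 7 in all. Adjustment was by Benjamini-Hochberg over the 3541 probe sets of each comparison, with a threshold of adjusted p under 0.05. Beside it the number of probe sets at an unadjusted p under 0.05 is given, of which chance gives 177. The number of probe sets whose groups do not overlap is given too, of which chance gives 10% for 3 arrays against 3 and 0.216% for 6 against 6.

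The 27 gene lists were written before the data were examined, as were the comparisons, the filter, the tests and the rule for naming genes. They cover activity-induced transcription factors, activity-induced effector genes, feedback regulators of MAP kinase signalling, the CREB family and its co-activators, sterol synthesis and uptake, fatty acid synthesis, the heat shock response, the unfolded protein response, the cytokine and innate immune response, glucocorticoid-responsive genes, the circadian clock, and apoptosis and p53 targets. They further cover glutamate receptors and the postsynaptic density, the presynaptic vesicle cycle, voltage-gated ion channels, oxidative phosphorylation, ribosomal proteins, and markers of astrocytes, oligodendrocytes, microglia, endothelium with pericytes and blood, choroid plexus and ependyma, interneurons, the dentate gyrus, CA1 and CA3 pyramidal cells and neighbouring brain regions, and sex-linked transcripts. Of the 1261 gene entries 1242 matched the gene table by symbol and 19 by synonym, and 191 different genes were measured above the filter. Lists with at least 5 measured genes (19 of 27) were tested with limma's camera at its preset inter-gene correlation of 0.01, with the brightest probe set of each gene, adjusted over the 19 lists of a comparison. The estimated-correlation value given beside it comes from camera with the correlation estimated for each list. Members of a list were also adjusted over the list alone.

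Creb1 and Crem are named first, in every group. Of the probe sets past the threshold, up to 10 with the largest rise and 10 with the largest fall are named, with 1 symbol and 1 probe set per gene and, for comparisons of 3 arrays against 3, no overlap between groups. From each list up to 4 members with the largest absolute difference may be named per comparison. Genes outside this rule are said in the text to have been chosen after their values were seen.

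Replicate numbers are shared between the groups, so it was checked whether arrays with the same number deviate together from their group means. Correlations of same-numbered arrays were 0.627, 0.383 and 0.458 for kainate in control mice, 0.479, 0.0448 and -0.0779 for kainate in mutant mice, 0.855, 0.47 and 0.482 for genotype after saline, and 0.578, 0.333 and 0.19 for genotype after kainate. The rule that each must exceed 0.1 was met in all of these but kainate in mutant mice. Yet arrays with different numbers reached 0.652 and 0.669 for genotype after saline, where the same number gave 0.47 and 0.482. They reached 0.249 and 0.359 for genotype after kainate, against 0.333 and 0.19. For kainate in control mice they reached 0.374 and 0.434, against 0.383 and 0.458. Only replicate 1 correlated negatively with all other numbers (highest -0.239). The values part replicate 1 from the rest and do not show pairing by number. The labels do not say what a number marks.

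The alternatives fixed in advance were no filter, a stricter filter at log2 6, trend and robust variance, quantile normalization again, median-centring of each array, the replicate number as a block, array weights, only the arrays of the groups compared, a 1.5-fold minimum, 1 probe set per gene, leaving out each array in turn, and for lists the estimated correlation, the fry rotation test and the mean of a gene's probe sets. After the data were seen, a block for replicate 1 against replicates 2 and 3 was added. That block was also run without the array labelled control kainate replicate 3, and without it and mutant kainate replicate 3. The fit of replicates 2 and 3 alone and gene-by-gene array weights were added as well.

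A genotype score per array was computed after the data were seen, from the 50 probe sets with the smallest p between genotypes on the 6 saline arrays with the batch as a block, as the mean position between the control and mutant saline means. The actin and Gapdh 3' minus 5' differences and the mean of 9 bacterial spike-in probe sets came from the control probe sets. Groups were also exchanged between arrays, giving 10 splits for 3 arrays against 3 and 100 drawn splits for the interaction and the averages. After the data were seen, the 32 splits that part every pair of same-numbered arrays were added for the averages.

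The fit was tested on simulated data with the size of the kept table, in 10 runs with 200 changed probe sets each. For kainate in control mice 42.7, 64.5 and 86.8% of changes of log2 0.5, 1 and 2 were recovered, for the interaction 31.0, 51.3 and 79.8%, and for the averaged kainate effect 52.7, 79.1 and 97.0%. False calls made up 6.04, 5.18 and 5.05% of the calls. The simulated noise was drawn independently for each probe set and array. With 200 changes at once the threshold is also easier to pass than where few probe sets change. These shares therefore do not give the power of the measured comparisons. Camera called a list of 20 genes shifted by 0.5 in 20 of 20 runs and 0 of 380 unchanged lists.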

Results

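Gene expression in the hippocampus was compared between control mice and mice lacking CREB and CREM, 1 hour after an injection of kainate or saline. The 12 arrays form 4 groups of 3, and each array holds RNA pooled from 3 animals. Values are log2 throughout, and every error on a difference is a standard error from the limma fit. Of 11868 probe sets, 3541 (29.8%) passed the filter on dim signal and were tested, and those with 1 gene symbol stand for 2387 genes.

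Creb1 and Crem, the genes of the deleted factors, were read by 1 probe set each above the dim filter. Creb1 had means of 4.88 ± 0.12 (SD, n = 3 arrays per group) in control saline, 4.85 ± 0.04 in control kainate, 5.01 ± 0.09 in mutant saline and 4.90 ± 0.10 in mutant kainate. Crem had means of 4.46 ± 0.08, 4.47 ± 0.09, 4.71 ± 0.11 and 4.57 ± 0.07 in the same groups. Over the arrays Creb1 ran from 4.77 to 5.11 and Crem from 4.37 to 4.83, so neither signal was lower in the mutant groups. The remaining probe sets of these genes lay below the filter, Creb1 at 1.67 to 1.79 and 3.08 to 3.26 and Crem at 3.28 to 3.48. The sources used here do not say whether any of these probes lies in the part removed by the deletion, so these levels test nothing about the genotype labels.

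Most of the variation between arrays followed something other than genotype or treatment. The array of mutant kainate replicate 3 lay alone on the first principal component (53.2% of the variance), had an SD of 1.52 against 1.71 to 1.78 on the others, and a 90th percentile of 5.31 against 5.75 to 6.03. The second component (22.9%) parted the replicate 1 arrays from replicates 2 and 3. Replicate 1 arrays of different groups correlated at 0.987 to 0.992 with each other and at 0.887 to 0.965 with the other arrays of their own group. Replicate 1 against replicates 2 and 3 is therefore treated below as a batch seen in the data, and values within each are given beside most of the pooled ones.

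The array labelled control kainate replicate 3 carried values like those of the mutant arrays. A genotype score was built on the 6 saline arrays from the 50 probe sets that best part the genotypes, 11 higher and 39 lower in mutants, with 0 at the control mean and 1 at the mutant mean. The score parts the saline arrays by construction. This array scored 0.93, the other 5 control arrays -0.174 to 0.157, mutant kainate replicate 3 1.43 and the other 5 mutant arrays 0.59 to 1.17. Gfap, the astrocyte filament gene, read 12.95 on it against 11.50 and 11.53 on the other control kainate arrays. Fbll1, a gene chosen after its values were seen, read 6.51 against 7.84 and 7.78. Mutant kainate replicate 3 read 11.55 for Gfap and 7.46 for Fbll1, near the control arrays, and 6.77 for Gm2115 and 7.77 for Anks1b, near the mutant arrays. It read below the mean of the other mutant kainate arrays on 88.9% of probe sets at log2 7 to 9 and 93.1% above 9. Low values on it are therefore no clear sign of genotype. Every comparison with control kainate below holds this array as labelled, and some counts, genes and lists are also given without it and without mutant kainate replicate 3.

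**Figure D1:**
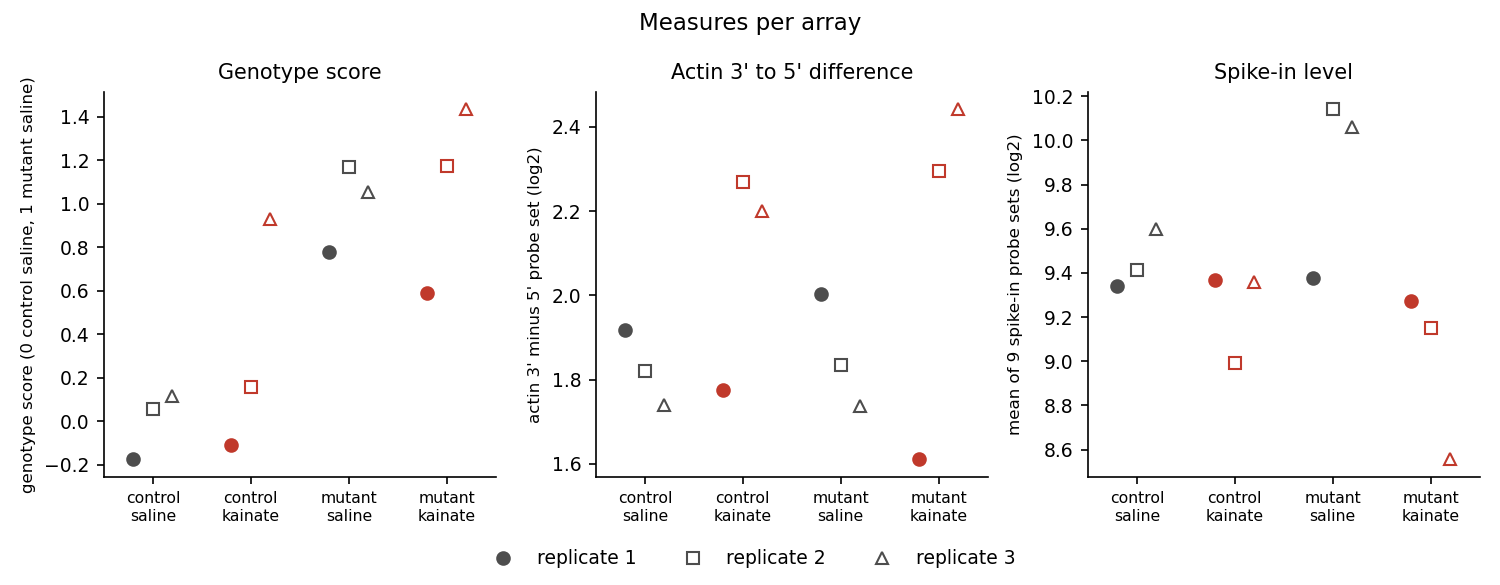
Genotype score, actin 3' minus 5' difference and mean of the spike-in probe sets (log2) on each of the 12 arrays, by group and replicate. The array labelled control kainate replicate 3 scores 0.93 among the mutants, the actin difference is 2.20 to 2.44 on kainate arrays of replicates 2 and 3, and the spike-in mean of mutant kainate replicate 3 is 8.56.

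In control mice kainate raised Kcnj2, which encodes an inward-rectifier potassium channel, 9.71-fold. Its mean went from 6.22 ± 0.32 to 9.50 ± 0.12 (SD, n = 3 arrays per group), a log2 difference of 3.28 ± 0.24 with all 3 kainate arrays above every saline array (adjusted p = 0.000649). The difference was 3.46 within replicate 1 and 3.19 within replicates 2 and 3. Kcnj2 was the only probe set of 3541 past the threshold (1 higher, 0 lower), with 158 at an unadjusted p under 0.05 where 177 are expected by chance. With the replicate number as a block 3 probe sets passed.

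Several genes induced by neuronal activity were also higher after kainate in control mice, none past the threshold over all probe sets. Apold1 was 2.55 ± 0.37 higher (adjusted p = 0.0678, 2.37 within replicate 1 and 2.64 within replicates 2 and 3), and Sik1, which encodes a salt-inducible kinase, was 1.89 ± 0.27 higher (adjusted p = 0.0678, 1.70 and 1.99). Gm13889 was higher on a probe set (2.41 ± 0.37, adjusted p = 0.0856, 2.67 and 2.28) that reads 1.75 to 2.36 on the saline arrays, below the dim level of 4, so the size of this difference has no meaning. Its brighter probe set gave 1.11 ± 0.33 (1.40 and 0.97). The zinc-finger factor Egr3 was 1.61 ± 0.26 higher (adjusted p = 0.102, 1.53 and 1.66). Egr4, of the same factor family, was 1.62 ± 0.48 higher (adjusted p = 1, 1.46 and 1.70), and Rgs4, a GTPase activator for G proteins, was 1.16 ± 0.21 higher (adjusted p = 0.215, 1.40 and 1.04). On all 3 kainate arrays each of these genes lay above every saline array. Without the array labelled control kainate replicate 3 and mutant kainate replicate 3, and with the batch as a block, 7 probe sets passed, among them Egr3 (1.59 ± 0.16, adjusted p = 0.0227), Apold1 (2.34 ± 0.25, adjusted p = 0.0308), Sik1 (2.17 ± 0.26, adjusted p = 0.0354) and Gm13889 (2.74 ± 0.33, adjusted p = 0.0354).

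Within the gene lists, some of these differences passed when adjusted over the list alone. Of 8 measured activity-induced transcription factors 2 passed higher and 0 lower, Egr3 (adjusted p = 0.0012 over the list alone) and Egr4 (adjusted p = 0.031), and 6 did not pass. Of 16 activity-induced effector genes 3 passed higher, Sik1 (adjusted p = 0.00086 over the list alone), Rgs4 (adjusted p = 0.0029) and Gm13889 by its second probe set (1.11 ± 0.33, adjusted p = 0.030). Cgref1 passed lower at -0.77 ± 0.23 (adjusted p = 0.030), with -0.11 within replicate 1 and -1.10 within replicates 2 and 3. Its call was lost with the batch as a block and without the 2 doubted arrays (adjusted p = 0.0603). The 9 astrocyte genes were the 1 list of 19 past the list test, 8 of them positive with a median difference of 0.22 (camera adjusted p = 0.0191, adjusted p = 0.361 with an estimated correlation, 0.0183 with the replicate number as a block). Its largest members were Gfap (0.84 ± 0.49, -0.09 within replicate 1 and 1.30 within replicates 2 and 3) and Apoe (0.59 ± 0.19, 0.04 and 0.87), which encodes a lipid carrier. Apoe reads 3.69 to 4.14 on the saline arrays, around the dim level of 4, so the size of its difference is uncertain. Without the 2 arrays named above the astrocyte list gave a median of 0.14 and an adjusted p of 0.242, and Gfap is among the genes on which the array labelled control kainate replicate 3 read like a mutant array.

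In mutant mice kainate raised Kcnj2 4.39-fold, from 6.73 ± 0.10 to 8.87 ± 0.52 (SD, n = 3 arrays per group), a log2 difference of 2.14 ± 0.24 with all 3 kainate arrays above every saline array (adjusted p = 0.027). The difference was 2.44 within replicate 1 and 1.98 within replicates 2 and 3. It was again the only probe set past the threshold (1 higher, 0 lower), with 300 at an unadjusted p under 0.05. For Kcnj2, kainate effect in mutant mice, the call was lost with no filter (adjusted p = 0.0831), with only the arrays compared (adjusted p = 0.804) and without any 1 of 8 arrays, over which the difference stayed at 1.96 to 2.19. Removing 1 array gave counts of 0 to 67. Gm13889 was higher on the probe set that is dim after saline (2.38 ± 0.37, adjusted p = 0.104, 1.37 within replicate 1 and 2.89 within replicates 2 and 3), Egr3 by 1.66 ± 0.26 (adjusted p = 0.104, 1.58 and 1.70), Sik1 1.60 ± 0.27 (adjusted p = 0.139, 1.44 and 1.68), Apold1 1.80 ± 0.37 (adjusted p = 0.395, 2.63 and 1.38) and Egr4 2.06 ± 0.48 (adjusted p = 0.579, 0.55 and 2.81), each above every saline array on 3 of 3 kainate arrays. Rgs4 was 0.46 ± 0.21 higher (1.14 and 0.11). In the fit with the batch as a block and without the 2 doubted arrays Kcnj2, Egr3, Sik1, Apold1, Egr4 and Rgs4 had 2.47, 1.73, 1.67, 2.22, 1.96 and 0.69. Of these Kcnj2 (adjusted p = 0.00122), Egr3 (adjusted p = 0.0128) and Apold1 (adjusted p = 0.0341) passed over all probe sets in that fit.

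The activity-induced transcription factors were the 1 list of 19 past the list test in mutant mice (8 measured genes, 5 positive, camera adjusted p = 0.0298, adjusted p = 0.214 with an estimated correlation, 0.0161 with the replicate number as a block). Its weight came from Egr3 (adjusted p = 0.00094 over the list alone) and Egr4 (adjusted p = 0.0075), with 2 genes passing higher, 0 lower and 6 not passing. Of the 16 effector genes Sik1 (adjusted p = 0.0031) and Gm13889 by its second probe set (1.65 ± 0.33, adjusted p = 0.0050) passed over the list alone, and 14 did not. Dynlrb2, a dynein light chain gene of ciliated cells, passed lower within the choroid plexus and ependymal list (-0.30 ± 0.08, adjusted p = 0.029, -0.17 within replicate 1 and -0.37 within replicates 2 and 3). This call was lost with the batch as a block and without the 2 doubted arrays (-0.23 ± 0.08, adjusted p = 0.128). Without the array labelled control kainate replicate 3 and mutant kainate replicate 3 the transcription factor list gave an adjusted p of 0.205.

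Averaged over the genotypes, kainate raised 5 probe sets of 3541 and lowered 0, and these are Kcnj2, Sik1, Gm13889, Egr3 and Apold1. Kcnj2 rose 6.53-fold (2.71 ± 0.17, n = 6 arrays against 6, adjusted p = 0.000162), Apold1 4.51-fold (2.17 ± 0.26, adjusted p = 0.0089), Sik1 3.36-fold (1.75 ± 0.19, adjusted p = 0.00704) and Egr3 3.11-fold (1.64 ± 0.19, adjusted p = 0.00704). Gm13889 passed (2.4 ± 0.26, adjusted p = 0.00704) on the probe set that is dim after saline, so no fold is given for it. For each of them 6 of 6 kainate arrays lay above every saline array. The differences within replicate 1 and within replicates 2 and 3 were 2.95 and 2.59 for Kcnj2, 2.02 and 2.59 for Gm13889, 2.50 and 2.01 for Apold1, 1.57 and 1.84 for Sik1, and 1.55 and 1.68 for Egr3. Without the 2 doubted arrays and with the batch as a block they were 2.87, 2.45, 2.28, 1.92 and 1.66 in the same order. With the block and only the array labelled control kainate replicate 3 left out, Kcnj2, Sik1, Gm13889 and Egr3 passed and Apold1 did not. Quantile normalization again gave 9 probe sets, 8 higher and 1 lower.

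**Figure D2:**
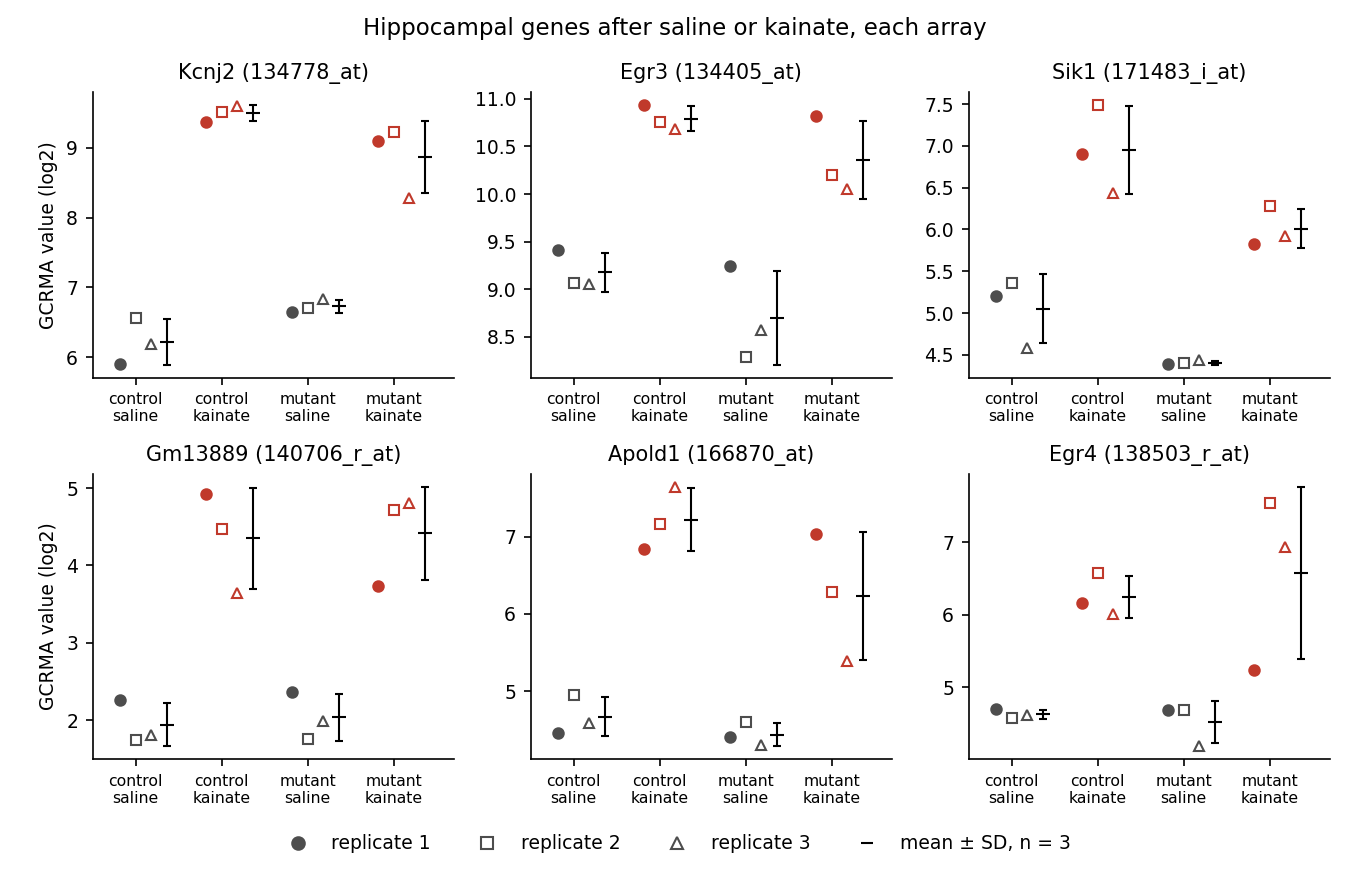
Log2 expression of Kcnj2, Sik1, Gm13889, Egr3, Apold1 and Egr4 on each array, with group mean and SD (n = 3 arrays per group), after saline (grey) and kainate (red). Kainate arrays lie above every saline array for each gene, and the averaged difference of Kcnj2 is 2.71.

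Other activity-induced genes were higher after kainate without passing over all probe sets with all arrays and no block. Egr4 was 1.84 ± 0.34 higher on 6 of 6 kainate arrays (adjusted p = 0.158, 1.01 within replicate 1 and 2.25 within replicates 2 and 3, over the list alone adjusted p = 0.0015), and Rgs4 0.81 ± 0.15 on 5 of 6 (adjusted p = 0.158, 1.27 and 0.57, over the list alone adjusted p = 0.0021). The second and brighter probe set of Gm13889 gave 1.38 ± 0.23 (adjusted p = 0.0934) and the second probe set of Egr3 1.20 ± 0.44 (2.26 and 0.67). With the batch as a block and without the 2 doubted arrays, choices made after the data were seen, 2 of these passed over all probe sets. They were Rgs4 (0.909 ± 0.135, adjusted p = 0.0459) and the brighter probe set of Gm13889 (1.285 ± 0.148, adjusted p = 0.0205). An unadjusted p under 0.05 was reached by 400 probe sets, against 177 expected. Every kainate array was above every saline array on 14 of the 3541 probe sets and below on 16, 0.847% together where chance gives 0.216%. Over all 11868 probe sets, dim ones included, it was 20 above and 17 below, where chance gives 12.8 for each. Both chance figures assume no array differences that follow the treatment, such as those of replicates 2 and 3 given below.

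On the averaged kainate effect the activity-induced transcription factors, of which 8 of 81 were measured, passed the list test (camera adjusted p = 0.0428, adjusted p = 0.178 with an estimated correlation, 0.0443 with the replicate number as a block, 0.152 without the 2 doubted arrays), with a mean difference of 0.355 carried by Egr3 and Egr4 and a median of -0.01 over the 8 genes. Of the effector genes, 16 of 103 were measured (camera adjusted p = 0.0841), and of these 3 passed higher and 2 lower over the list alone, the lower ones being Cgref1 (-0.59 ± 0.16, adjusted p = 0.018, -0.09 within replicate 1 and -0.84 within replicates 2 and 3) and Cpeb4 (-0.65 ± 0.22, adjusted p = 0.046, -0.25 and -0.86). Cpeb4 reads 4.30 to 4.82 on the kainate arrays, near the dim level of 4, so the size of its difference is uncertain. Among the 8 feedback regulators of MAP kinase signalling (camera adjusted p = 0.93) Rgs4 passed higher and the pseudokinase gene Peak1 lower (-0.56 ± 0.18, adjusted p = 0.047, -0.39 and -0.65). Peak1 did not pass with the batch as a block and without the 2 doubted arrays (-0.34 ± 0.11, adjusted p = 0.0824). The 4 measured genes of the CREB family and its co-activators were too few for the list test, and of them the co-activator Crtc3 passed lower over the list alone (-0.34 ± 0.10, adjusted p = 0.035, -0.21 and -0.41) while Crtc1 did not pass (0.39 ± 0.16).

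Astrocyte genes formed the other list past the test on the averaged kainate effect (7 of 9 positive, camera adjusted p = 0.0184, adjusted p = 0.178 with an estimated correlation, 0.0252 with the replicate number as a block, 0.152 without the 2 doubted arrays). Apoe (0.51 ± 0.13, adjusted p = 0.017) and Pla2g7 (0.25 ± 0.06, adjusted p = 0.017) passed higher over the list alone, and 7 genes did not pass. Both calls were lost with the batch as a block and without the 2 doubted arrays (0.43 ± 0.16 and 0.25 ± 0.08, each with adjusted p = 0.138). Apoe lies around the dim level on the saline arrays. Both differences came from replicates 2 and 3, at 0.77 for Apoe and 0.35 for Pla2g7 against -0.01 and 0.04 within replicate 1. Gfap was 0.37 ± 0.35 higher (-0.14 and 0.62). In replicates 2 and 3 the actin 3' minus 5' difference, a measure of RNA quality, was also 0.519 higher on the kainate arrays, with no overlap.

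Synaptic, channel and metabolic genes gave no list past the threshold on the averaged kainate effect. Of 15 presynaptic vesicle genes (camera adjusted p = 0.943) the synapsin genes went apart over the list alone, Syn1 higher (0.51 ± 0.14, adjusted p = 0.038, 0.09 within replicate 1 and 0.72 within replicates 2 and 3) and Syn2 lower (-0.31 ± 0.08, adjusted p = 0.038, -0.19 and -0.36). The other probe sets of Syn2 gave -0.07 and 0.04 and lend this fall no weight. That at -0.07 was higher after kainate in control mice (means of 10.853 and 11.11). In mutants it read 10.005 on the weak array of mutant kainate replicate 3 against 11.317 and 11.023 on the other mutant kainate arrays. That at 0.04 reads 3.97 to 4.21 over the arrays, around the dim level, so its direction says little. Of 23 genes on the voltage-gated channel list (camera adjusted p = 0.93) Kcnj2 alone passed. The list also holds inward rectifiers, of which Kcnj2 is one. Of 12 glutamate receptor and postsynaptic density genes (camera adjusted p = 0.943) none passed. Oxidative phosphorylation had 2 of 10 genes positive and a median of -0.33 (camera adjusted p = 0.476), led by the respiratory complex genes Ndufs1 (-1.16 ± 0.48, 0.02 and -1.75) and Cox7a2 (-0.62 ± 0.21, -0.11 and -0.87). Without the 2 doubted arrays the median of this list was -0.08, and Ndufs1 read 4.96 on the weak array of mutant kainate replicate 3 against 8.23 and 6.65 on the other mutant kainate arrays. The 8 sterol synthesis and uptake genes gave a camera adjusted p of 0.505, with Mvd of the mevalonate pathway at 0.73 ± 0.25 (-0.01 and 1.10). Mvd reads 3.97 to 4.20 on the saline arrays, around the dim level of 4, so the size of its difference is uncertain. The 6 apoptosis and p53 target genes gave a camera adjusted p of 0.612, with the caspase inhibitor gene Xiap at -0.80 ± 0.26 (0.04 and -1.22), and the 5 glucocorticoid-responsive genes gave 0.943.

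Markers of other cell types and regions did not pass the list test on the averaged kainate effect either. Camera adjusted p was 0.943 for 6 oligodendrocyte genes, 0.93 for 6 microglia genes, 0.943 for 6 endothelial, pericyte and blood genes, 0.679 for 7 choroid plexus and ependymal genes, 0.93 for 7 interneuron genes, 0.93 for 12 dentate gyrus genes, 0.612 for 7 CA1 and CA3 pyramidal genes and 0.612 for 9 genes of neighbouring brain regions. Dynlrb2 passed lower over its list alone (-0.26 ± 0.06, adjusted p = 0.0089, -0.13 within replicate 1 and -0.32 within replicates 2 and 3). It did not with the batch as a block and without the 2 doubted arrays (-0.21 ± 0.06, adjusted p = 0.0558). Too few genes were measured for a list test of fatty acid synthesis (2), the heat shock response (3), the unfolded protein response (2), cytokines and innate immunity (2), the circadian clock (2), ribosomal proteins (4) and sex-linked transcripts (2). Their median kainate differences were -0.16, -0.49, -0.02, 0.04, -0.05, 0.06 and -0.04. The heat shock gene Hspa4l passed lower over its list alone (-0.55 ± 0.17, adjusted p = 0.032, 0.05 and -0.85).

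Most probe sets called for kainate in replicates 2 and 3 alone showed little of that difference in replicate 1. There 205 probe sets passed (56 higher, 149 lower), of which 53.2% had the same sign in replicate 1. Their median share of the difference in replicate 1 was 0.0143 (quartiles -0.109 and 0.15). Over the 3541 probe sets the averaged kainate difference of replicate 1 correlated at 0.0881 with that of replicates 2 and 3, while control and mutant correlated at 0.546 within replicates 2 and 3 and at 0.366 within replicate 1.

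**Figure D3:**
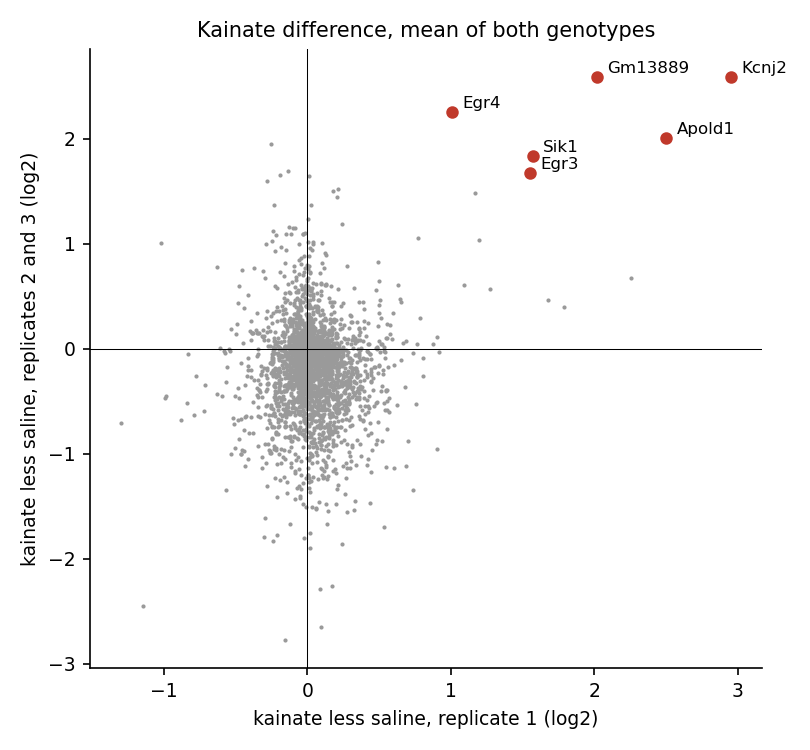
Log2 kainate less saline difference, averaged over genotypes, of each of 3541 probe sets in replicate 1 (n = 1 pair of arrays per genotype) against replicates 2 and 3 (n = 2 pairs per genotype). Kcnj2, Gm13889, Apold1, Sik1 and Egr3 are high in both, and the correlation over all probe sets is 0.0881.

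The series set out to find how loss of CREB and CREM alters the response to kainate, and no probe set passed the test of that interaction. The limma fit called 0 of 3541 (lowest adjusted p = 0.973), with 31 at an unadjusted p under 0.05 where 177 are expected. This fit has no block, so differences between the replicate batches and the weak array of mutant kainate replicate 3 enter its spread. A count so far below expectation means that these p-values run high. The 0 calls therefore do not show that the responses are alike. Kcnj2, raised in both genotypes, had an interaction of -1.15 ± 0.34 (adjusted p = 0.973, 0.183 adjusted over the channel list alone), with -1.02 within replicate 1 and -1.21 within replicates 2 and 3. With the batch as a block and without the 2 doubted arrays it was -0.80 ± 0.19, and in the same fit Rgs4, Apold1 and Kcnq5, given next with all arrays, had -0.43, -0.11 and -0.15. Rgs4 had -0.70 ± 0.30 (-0.26 and -0.92), Apold1 -0.75 ± 0.52 (0.26 and -1.26) and the potassium channel gene Kcnq5 -1.0 ± 0.94 (0.03 and -1.51). The second probe set of Kcnq5 had 0.19 but lies near the dim level, at 4.45 and 4.46 on mutant kainate replicates 1 and 2. It read 5.02 on the weak array of mutant kainate replicate 3, so its direction says little. Egr3 at 0.04 ± 0.37 and Sik1 at -0.29 ± 0.38 show how much difference the arrays leave open for the genes kainate raised, and without the 2 doubted arrays they had 0.14 ± 0.22 and -0.50 ± 0.37. The second probe set of Egr3 (-0.45) disagrees in direction with the first, and the brighter probe set of Gm13889 had 0.54 ± 0.46 with all arrays and -0.01 ± 0.29 without those. None of the 19 lists passed (lowest camera adjusted p = 0.594, adjusted p = 0.897 with an estimated correlation).

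After saline, several genes lay lower or higher on every mutant array than on every control array, without passing the threshold over all probe sets. The following 6 genes were chosen after their values were seen. Fbll1, a fibrillarin-like gene, was lower by -1.48 ± 0.37 (adjusted p = 0.385, -1.13 within replicate 1 and -1.66 within replicates 2 and 3). Anks1b, which encodes a postsynaptic scaffold protein, had lower means on all 5 of its kept probe sets, the largest differences being -1.35 ± 0.37 (-1.36 and -1.35) and -1.15 ± 0.27 (-1.07 and -1.19). Gm2115 had -1.32 ± 0.40 (-1.24 and -1.36), the mitochondrial carrier gene Slc25a16 -0.90 ± 0.37 (-0.85 and -0.92) and the somatostatin receptor gene Sstr4 -0.87 ± 0.29 (-0.85 and -0.88). Csgalnact1, an enzyme gene of chondroitin sulphate synthesis, had the lowest adjusted p (0.0747) at 0.54 ± 0.07 (0.54 and 0.54). Each of these differences held on 3 of 3 mutant saline arrays, beyond every control saline array, while 1 further probe set of Anks1b (-0.60) did so on 1 of 3.

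The limma fit called 0 of 3541 probe sets for genotype after saline, with 428 at an unadjusted p under 0.05 where 177 are expected. The groups did not overlap for 1027 probe sets higher and 181 lower in mutants, 34.1% where chance gives 10%. Over all probe sets the difference after saline leaned upward, with a median of 0.0379 and 58.7% positive. The array median, which includes the dim probe sets, was 3.318 to 3.373 on mutant saline arrays and 3.264 to 3.285 on control saline arrays. The 10% assumes no such shift between arrays, so the excess without overlap cannot be read as changes of single genes. With the batch as a block and without the array labelled control kainate replicate 3 and mutant kainate replicate 3, which only enter the estimate of the spread here, 6 probe sets passed lower and 0 higher. These were Slc25a16 (-0.90 ± 0.05, adjusted p = 0.00166), Gm2115 (-1.32 ± 0.10, adjusted p = 0.00377), Fbll1 (-1.48 ± 0.11, adjusted p = 0.00377), Anks1b (-1.15 ± 0.09, adjusted p = 0.00377, and -1.35 ± 0.14, adjusted p = 0.0193) and Sstr4 (-0.87 ± 0.10, adjusted p = 0.0307). The first of these arrays was doubted on genes of this kind, so leaving it out narrows their spread and these calls are no independent test.

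Among list genes after saline, Gfap was higher in mutants by 1.41 ± 0.49 (adjusted p = 0.385, 1.41 within replicate 1 and 1.40 within replicates 2 and 3, 3 of 3 arrays). Laptm5, a lysosomal membrane protein gene of microglia, had 0.67 ± 0.40 (0.89 and 0.56), and P2ry12, the microglial purine receptor gene, 0.14 ± 0.10. Among neuronal genes the sodium channel subunit gene Scn3b stood at -0.56 ± 0.18 (-0.57 and -0.55) and -0.66 ± 0.76 on its second probe set, Camk2d at -0.51 ± 0.41 (-0.03 and -0.75), Pclo at -0.51 ± 0.46 (-0.42 and -0.56), the glutamate transporter gene Slc17a6 at -0.49 ± 0.27 (-0.09 and -0.68) and Syt4 at -0.44 ± 0.29 (-0.29 and -0.52). Creb1 differed by 0.12 ± 0.08 and Crem by 0.24 ± 0.08. Probe sets of both below the filter were also higher, with means of 3.172 against 3.101 (Creb1) and 3.387 against 3.305 (Crem). These differences therefore cannot be told apart from the shift between arrays given above. None of the 19 lists passed, the lowest being presynaptic vesicle genes in the lower direction (camera adjusted p = 0.189, adjusted p = 0.834 with an estimated correlation).

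**Figure D4:**
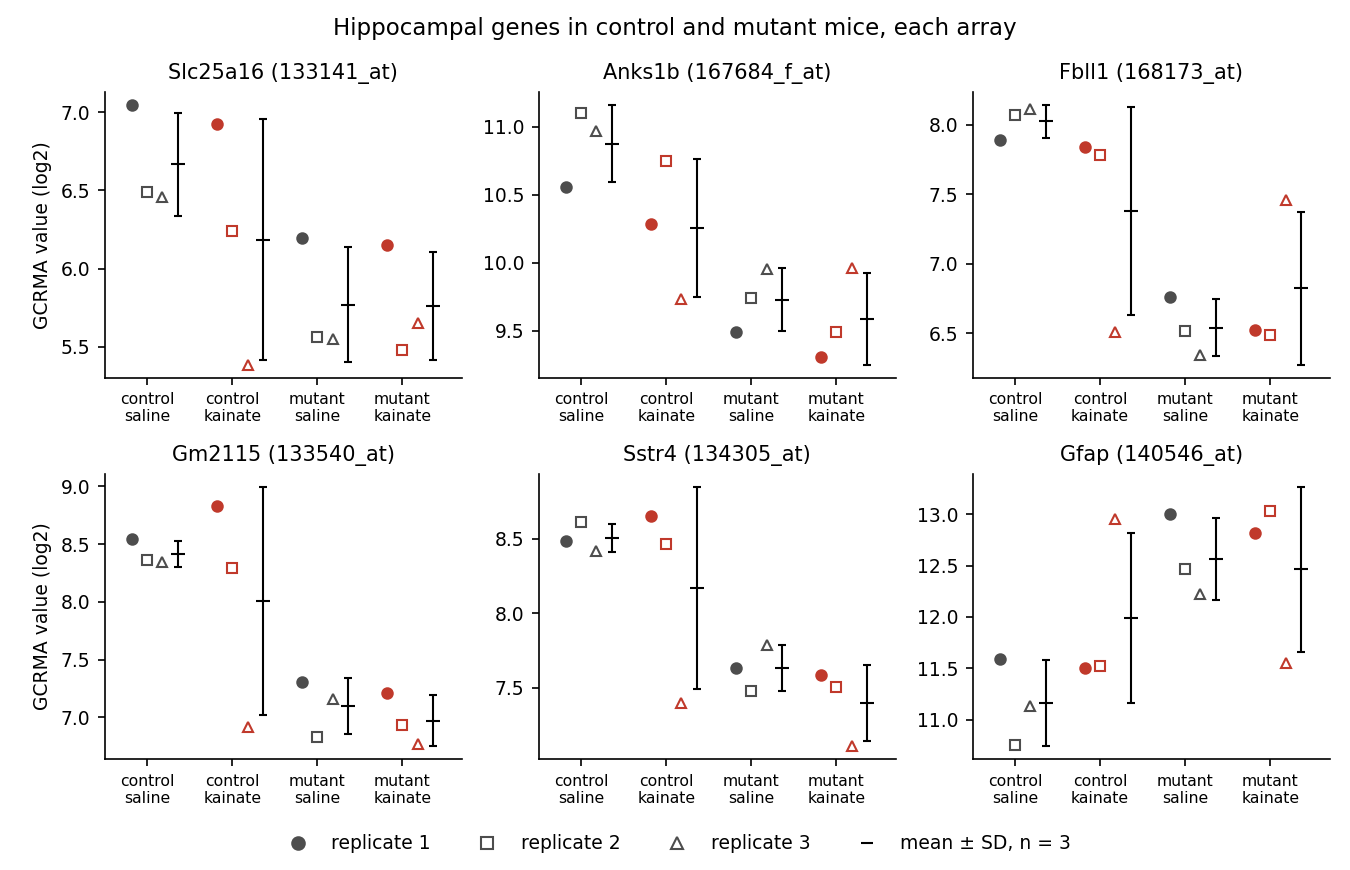
Log2 expression of genes that part the genotypes after saline on each array, with group mean and SD (n = 3 arrays per group), after saline (grey) and kainate (red). On the array labelled control kainate replicate 3, Gfap reads 12.95 and Fbll1 6.51, near the mutant saline arrays, while mutant kainate replicate 3 reads 11.55 and 7.46.

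After kainate no genotype difference passed with the arrays as labelled. The limma fit called 0 of 3541 probe sets (lowest adjusted p = 0.55), with 167 at an unadjusted p under 0.05, and the groups did not overlap for 86 higher and 134 lower, 6.21% where chance gives 10%. Anks1b was lower by -1.03 ± 0.37 (-1.29 within replicate 1 and -0.90 within replicates 2 and 3) and -0.67 ± 0.27 (-0.98 and -0.51), Gm2115 by -1.04 ± 0.40 (-1.61 and -0.75), Fbll1 by -0.56 ± 0.37 (-1.31 and -0.17) and Slc25a16 by -0.42 ± 0.37 (-0.78 and -0.25). Csgalnact1, higher in mutants after saline, had 0.07 ± 0.07 after kainate (-0.06 and 0.14) and an interaction of -0.47 ± 0.10 (adjusted p = 0.973, -0.60 and -0.40, and -0.51 with the block and without the 2 doubted arrays). With the batch as a block and without the 2 doubted arrays 4 probe sets passed lower, Gm2115 (-1.49 ± 0.13, adjusted p = 0.013), Slc25a16 (-0.77 ± 0.06, adjusted p = 0.013), Anks1b (-1.12 ± 0.11, adjusted p = 0.0207) and Fbll1 (-1.31 ± 0.14, adjusted p = 0.0249). The array labelled control kainate replicate 3 was left out because it reads like a mutant on such genes, so these calls follow in part from that choice.

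Of the 23 genes on the voltage-gated channel list 3 were positive for genotype after kainate, with a median of -0.42 (camera adjusted p = 0.138, adjusted p = 0.782 with an estimated correlation). Without the 2 doubted arrays 7 were positive and the median was -0.24, and mutant kainate replicate 3 read lower than its group on most bright probe sets. The list passed with the replicate number as a block (0.0141) and not without the 2 doubted arrays (0.0841). Among its members were Kcnq5 (-1.09 ± 0.67, 0.06 within replicate 1 and -1.66 within replicates 2 and 3, with 0.20 on its second probe set near the dim level), Kcnj2 (-0.63 ± 0.24, -0.28 and -0.81) and the sodium channel gene Scn8a (-0.56 ± 0.31, -0.14 and -0.77). Gfap was 0.47 ± 0.49 higher (1.31 and 0.05). With the batch as a block and without the 2 doubted arrays Kcnq5, Kcnj2, Scn8a and Gfap had -0.24, -0.29, -0.33 and 1.41.

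Averaged over the treatments, the limma fit called 0 of 3541 probe sets for genotype (lowest adjusted p = 0.247), with 677 at an unadjusted p under 0.05 where 177 are expected. Every mutant array was above every control array on 12 probe sets and below on 12, 0.678% where chance gives 0.216%. Mogs, which encodes the glucosidase that starts N-glycan trimming, had -1.34 ± 0.30 (-1.50 within replicate 1 and -1.26 within replicates 2 and 3) and the potassium channel gene Kcnq3 -0.86 ± 0.22 (-0.60 and -0.99). Anks1b had -1.19 ± 0.26 (-1.32 and -1.12) and -0.91 ± 0.19 (-1.02 and -0.85), Gm2115 -1.18 ± 0.28 (-1.43 and -1.05), Fbll1 -1.02 ± 0.26 (-1.22 and -0.92), Sstr4 -0.82 ± 0.20 (-0.96 and -0.75), Slc25a16 -0.66 ± 0.26 (-0.82 and -0.58) and Kctd4 -0.66 ± 0.19 (-0.61 and -0.69). Mogs and Kctd4 were also chosen after their values were seen. A brighter probe set of Kcnq3 differed less, with means of 10.149 and 10.115 in control saline and kainate and 9.845 and 9.692 in mutant saline and kainate. The other kept probe sets of Kctd4 also had lower mutant means, with smaller differences.

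Within the lists, Sik1 was lower in mutants over the treatments (-0.79 ± 0.19, over the list alone adjusted p = 0.039, -0.95 within replicate 1 and -0.71 within replicates 2 and 3), and 15 of 16 effector genes did not pass. Jun (0.15 ± 0.04, adjusted p = 0.046, 0.06 and 0.19) and the X-linked gene Kdm5c (0.20 ± 0.07, adjusted p = 0.033, 0.05 and 0.28) passed higher over their lists alone. Neither did so with the batch as a block and without the 2 doubted arrays (0.13 ± 0.05, adjusted p = 0.0694, and 0.15 ± 0.07, adjusted p = 0.118). Jun reads 3.99 to 4.27 over the arrays, at the dim level. Kdm5c reads 4.62 to 5.11, not far above that level. Its probe set below the filter was also higher in mutants, with means of 3.883 against 3.815 after saline and 3.894 against 3.823 after kainate. Scn3b had -0.52 ± 0.13 (-0.46 and -0.55), the complex subunit gene Ndufs4 -0.95 ± 0.33 (-0.53 and -1.15), the sterol reductase gene Tm7sf2 -0.80 ± 0.31 (-0.67 and -0.87), Slc17a6 -0.53 ± 0.19 (-0.23 and -0.69), Syt4 -0.51 ± 0.20 (-0.24 and -0.65) and Gfap 0.94 ± 0.35 (1.36 and 0.73). Creb1 differed by 0.09 ± 0.06 and Crem by 0.17 ± 0.06 (adjusted p = 0.247). Their probe sets below the filter limit the reading here as they do after saline. None of the 19 lists passed, presynaptic vesicle genes again giving the lowest value in the lower direction (camera adjusted p = 0.184).

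With the batch as a block and without the array labelled control kainate replicate 3 and mutant kainate replicate 3, 29 probe sets passed for genotype over the treatments, 3 higher and 26 lower. Gfap rose by 1.41 ± 0.17 (adjusted p = 0.0208) and Laptm5 by 0.64 ± 0.10 (adjusted p = 0.0488). The lower ones include Slc25a16 (-0.83 ± 0.04, adjusted p = 0.000546), Gm2115 (-1.40 ± 0.08, adjusted p = 0.000837), Fbll1 (-1.39 ± 0.09, adjusted p = 0.000837), Anks1b (-1.13 ± 0.07, adjusted p = 0.000837), Sstr4 (-0.94 ± 0.08, adjusted p = 0.00382), Kctd4 (-0.66 ± 0.07, adjusted p = 0.0115), Mogs (-1.56 ± 0.16, adjusted p = 0.0117), Tm7sf2 (-0.59 ± 0.08, adjusted p = 0.0315) and Kcnq3 (-0.77 ± 0.11, adjusted p = 0.039). Sik1 had -0.89 ± 0.18 in that fit (adjusted p = 0.089). The block and the leaving out of arrays were both chosen after the data were seen, the latter on genes of this kind, and the calls rest on the pair of choices. The block alone gave 0 probe sets, and leaving out the array labelled control kainate replicate 3 without the block gave 2.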

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

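The search below the dim filter was fixed before the data were examined, while the values per array were looked at only after its result was seen. Of 213 probe sets of list genes below the filter, 1 had every kainate array above or below every saline array, where 0.461 are expected by chance, and 0 parted the genotypes. This was Arc, the activity-regulated cytoskeleton gene, at 0.98 (log2) higher on the mean of the kainate arrays, on 6 of 6. The saline arrays read 2.87 to 2.97 and the kainate arrays 2.98 to 5.23, with 3.98, 2.98 and 4.72 in control mice and 5.23, 3.49 and 3.08 in mutants. Most of these values lie below the dim level of 4, so the size of the difference has no meaning. It is named because a signal appeared in data that the comparisons leave out, and it was not tested there.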

How the results depend on the processing

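The settings with a batch block, with replicates 2 and 3 alone and with gene-by-gene arrayWeights were chosen after the data were seen, and the others before. All values are counts of probe sets past the threshold unless said otherwise, and the number tested was 11868 with no filter, 1267 with the stricter filter and 2387 with 1 probe set per gene. The default arrayWeights stopped before converging and gave mutant kainate replicate 2 a weight of 28.8 against 0.0567 for replicate 3, so its counts say little. The gene-by-gene method gave 3.01 and 0.0968. Median-centring moved the median kainate difference in mutants from -0.0846 to 0.0403 and the genotype difference after kainate from -0.031 to 0.0757.

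The kainate effect in control mice had 1 as reported, against stricter filter 4, quantile-normalized again 2, median-centred 5, replicate block 3, only the arrays of the groups compared 6, 1 probe set per gene 3, batch block 2, batch block with control kainate array 3 left out 2, and with mutant kainate array 3 left out as well 7. Replicates 2 and 3 alone gave 14 (4 higher, 10 lower), arrayWeights 113 (43 higher, 70 lower) and arrayWeights gene by gene 51 (22 higher, 29 lower). No filter, trend and robust and the 1.5-fold minimum gave 1. Without each array in turn it was 1 to 4, with 4 without mutant kainate replicate 1 and 3 without control kainate replicate 3 or mutant kainate replicate 3.

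The kainate effect in mutant mice had 1 as reported, against no filter 0 (422 at an unadjusted p under 0.05 in limma), only the arrays of the groups compared 0 (113), quantile-normalized again 4, median-centred 2, replicate block 2, batch block 2, and 5 with control kainate array 3 and mutant kainate array 3 left out. Replicates 2 and 3 alone gave 70 (16 higher, 54 lower), arrayWeights 1007 (292 higher, 715 lower) and arrayWeights gene by gene 26 (13 higher, 13 lower). Removing 1 array gave 0 to 67. It was 67 without mutant kainate replicate 1, 3 without mutant kainate replicate 3, and 0 without control saline replicate 3, any control kainate array, any mutant saline array or mutant kainate replicate 2.

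The genotype by kainate interaction had 0 as reported, against arrayWeights 2 (1 higher, 1 lower), and 0 under the other settings and without any 1 array. The genotype effect after saline had 0 as reported, against arrayWeights 2 and gene by gene 2 (both higher), batch block with control kainate array 3 left out 4, and with mutant kainate array 3 left out as well 6 (all lower). The 12 fits without 1 array gave 0 throughout.

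The genotype effect after kainate had 0 as reported, against batch block with control kainate array 3 left out 3, with mutant kainate array 3 left out as well 4, replicates 2 and 3 alone 5 (all lower), arrayWeights 477 (174 higher, 303 lower) and gene by gene 4. Dropping each array once gave 0 to 15, with 15 without mutant kainate replicate 1. The genotype effect averaged over treatments had 0 as reported, against batch block with control kainate array 3 left out 13 (all lower), with mutant kainate array 3 left out as well 29 (3 higher, 26 lower), arrayWeights 938 (672 higher, 266 lower) and gene by gene 6. Over the fits without 1 array it was 0 to 2, with 2 without control kainate replicate 3 and 1 without mutant kainate replicate 1.

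The kainate effect averaged over genotypes had 5 as reported, against quantile-normalized again 9 (8 higher, 1 lower), batch block with control kainate array 3 and mutant kainate array 3 left out 20 (16 higher, 4 lower), replicates 2 and 3 alone 205 (56 higher, 149 lower), arrayWeights 1018 (350 higher, 668 lower) and gene by gene 482 (169 higher, 313 lower). The remaining settings gave 4 to 6. Without each array in turn it was 5 to 56, with 56 without mutant kainate replicate 1 and 11 without mutant kainate replicate 3.

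Of the named genes the smallest interactions changed sign. Egr3 had -0.087 with arrayWeights and -0.017 gene by gene, and Sik1 0.089 quantile-normalized again. The Gm13889 probe set that is dim after saline had a negative interaction with all arrays, unlike the brighter one. It had 0.11 quantile-normalized again, 0.075 median-centred, 0.43 with arrayWeights, 0.33 gene by gene and 0.61 in replicates 2 and 3 alone. The size of its differences has no meaning. Across the fits without 1 array Egr3 ran from -0.19 to 0.31 and this probe set of Gm13889 from -0.38 to 0.32. For Kcnj2, kainate effect in mutant mice, the threshold was missed with no filter (adjusted p = 0.0831), with only the arrays of the groups compared (0.804), in replicates 2 and 3 alone (0.0528), with the batch block and control kainate array 3 left out (0.0982), and without any 1 of the 8 arrays whose removal gives 0 above. Over its alternatives the adjusted p ran from 1.78e-06 to 0.804. For Apold1, kainate effect averaged over genotypes, it ran from 1.06e-05 to 0.0789.

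For the gene lists, counted as those past the threshold, the kainate effect in control mice had 1 as reported, against estimated inter-gene correlation 0, fry directional 0, fry mixed 4, batch block with control kainate array 3 left out 0, and with mutant kainate array 3 left out as well 0. Removing 1 array gave 0 to 1, with 0 without control saline replicate 1, control kainate replicate 2 or control kainate replicate 3. The kainate effect in mutant mice had 1 as reported, against estimated inter-gene correlation 0, no filter 0, fry directional 0, fry mixed 4, and batch block with control kainate array 3 and mutant kainate array 3 left out 0. The 12 fits without 1 array gave 0 to 3, with 3 without mutant kainate replicate 2, 2 without mutant saline replicate 3, and 0 without mutant saline replicate 1 or 2 or mutant kainate replicate 1 or 3.

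For the gene lists, the kainate effect averaged over genotypes had 2 as reported, against estimated inter-gene correlation 0, no filter 0, stricter filter 1, fry directional 1, fry mixed 5, batch block with control kainate array 3 left out 1, and with mutant kainate array 3 left out as well 0. Dropping each array once gave 0 to 3, with 3 without control saline replicate 2, 0 without control saline replicate 1 or mutant kainate replicate 3, and 1 without control kainate replicate 1 or 2 or mutant saline replicate 1 or 2.

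For the gene lists, the genotype by kainate interaction had 0 as reported, against no filter 1. The genotype effect after saline had 0 as reported, against no filter 1. The genotype effect after kainate had 0 as reported, against no filter 4, replicate block 1, batch block 1, batch block with control kainate array 3 left out 1. Over the fits without 1 array it was 0 to 1, with 1 without control kainate replicate 3 or mutant kainate replicate 1. The genotype effect averaged over treatments had 0 as reported, against no filter 4.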

Other observations

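The tests of the array patterns below and the splits that part every pair of same-numbered arrays in the averaged comparisons were chosen after the results were seen, while the other exchanges of group labels were fixed before. With the arrays as labelled, Kcnj2, Sik1, Gm13889, Egr3 and Apold1 rose after kainate in both batches, and Sik1 was lower in mutants averaged over the treatments when adjusted over its list alone.

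The array labelled control kainate replicate 3 reads like a mutant array. Its genotype score of 0.93 lies within the range of the arrays labelled mutant, as a wrong label or mutant tissue in the pool would give, and 8 of 11 probe sets higher and 31 of 39 lower in mutant saline lie beyond both other control kainate arrays. A change of signal shared by all probe sets of like brightness is argued against, since 0 of 1000 random sets of like brightness reached its signed mean of 0.668 (highest 0.219). The random sets were not matched for variability between arrays. A shift of probe sets that vary together is therefore not covered by this test. A swap with mutant kainate replicate 1 or 2 is argued against, as they score 0.59 and 1.17 against 0.157 for the highest of the other controls. For the mutant saline arrays the score cannot decide, because they helped to choose its probe sets and to set its scale. A swap with mutant kainate replicate 3 cannot be told apart from its absence, because once the trend with brightness is removed that array correlates with the saline genotype difference at 0.0267 on 20 probe sets, between controls (-0.913 to -0.494) and mutants (0.609 to 0.926), and at 0.393 on 50, within the mutants (0.342 to 0.898), and its residual spread is 0.33. Its values go both ways, with Gfap (11.55) and Fbll1 (7.46) near the controls and Gm2115 (6.77) and Anks1b (7.77) near the mutants. Low values of Gfap, Gm2115 and Anks1b can also come from its low reading of bright probe sets. On a brighter Anks1b probe set it read 9.96, the highest of the arrays labelled mutant and below the control arrays other than the doubted one (lowest 10.29). No biological explanation was tested, since the design gives none for a single array.

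Mutant kainate replicate 3 stands apart from all other arrays. Its spike-in mean of 8.56 is the lowest (others 8.99 to 10.1), which is consistent with weaker signal on this array. Its median difference from the other mutant kainate arrays was 0.0944 for 1806 probe sets below log2 5, -0.485 for 1015 at 5 to 7, -1.13 for 532 at 7 to 9 and -0.74 for 188 above 9. Degraded RNA stays open, as its Gapdh 3' minus 5' difference of 0.233 is below the 0.322 of mutant kainate replicate 2 by less than the spread within groups (0.146), while its actin difference is the highest. No biological explanation was tested for a single array.

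Most probe sets called for kainate in replicates 2 and 3 alone show little of that difference in replicate 1. A response to kainate common to all pools is argued against for these 205 probe sets as a set, whose median share in replicate 1 is 0.0143 (upper quartile 0.15). RNA quality or labelling that differs between saline and kainate arrays would give such an actin 3' minus 5' difference. It was 0.519 higher on kainate arrays in replicates 2 and 3 with no overlap and -0.268 in replicate 1. In replicates 2 and 3 the spike-in mean was also lower on kainate arrays (8.56 to 9.36 against 9.41 to 10.1). The Gapdh difference was higher there (0.123 to 0.322 against 0.011 to 0.119). Within replicate 1 both measures overlapped between the treatments. Array signal and treatment therefore cannot be parted in replicates 2 and 3. Kainate itself acting differently on the pools of replicate 1, for example through weaker seizures, stays open and was not tested, and the rise of Kcnj2 in both batches (2.95 and 2.59) shows that these pools did respond.

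For the averaged kainate effect, 3 of 100 splits gave as many as the 5 probe sets called, a share under the 0.05 fixed before, yet the highest other split gave 46. That split puts every replicate 1 array on the same side, which points to the batch structure of the arrays, and with the batch as a block the real split gives 6. The 100 splits ignore the replicate numbers, so with arrays that differ by batch their share does not measure chance. Of the 32 splits that part every pair of same-numbered arrays 1 gave as many, the real one, with 0 as the highest other. At an unadjusted p under 0.05 the 400 probe sets were reached by 2 of these 32, the real one included (highest other 423), so chance is not excluded for that excess. For the interaction 100 of 100 splits gave as many as the 0 called (highest other 0), and for genotype over the treatments 100 of 100 (highest other 2, from exchanging the arrays labelled control kainate replicate 3 and mutant kainate replicate 3). A count of 0 is reached by every split by construction, so these say nothing about chance. The 677 probe sets at an unadjusted p under 0.05 for genotype over the treatments were reached by 2 of the 32 splits, the real one included (highest other 792), so chance is not excluded for that excess.

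For comparisons of 3 arrays against 3 the 10 splits are too few for a share under 0.05. Kainate in control mice had 1 call, given by 1 of the 10 splits (highest other 0), and kainate in mutant mice 1 call, given by 1 of 10 (highest other 0). Genotype after saline had 0 calls, matched by construction by 10 of 10 splits (highest other 3), and genotype after kainate 0 calls, likewise matched by 10 of 10 (highest other 1, from exchanging the arrays labelled control kainate replicate 3 and mutant kainate replicate 3). Among splits parting as many pairs of same-numbered arrays as the real one, the highest were 0, 0 and 1 for kainate in control mice, genotype after saline and genotype after kainate.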
